A study of Caenorhabditis elegans with 8 samples.

How the data were processed

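Whole hermaphrodites of the wild-type strain N2 labelled adult day 1 and adult day 5 were compared, with 4 libraries each. Per the labels' protocols, synchronized first-stage larvae were grown at 20 °C for 60 h or 180 h, total RNA was extracted with TRIzol, and libraries were made from poly(A)-selected mRNA with the NEBNext Ultra kit, for which no strand marking is stated. The labels disagree in places: the design text gives the day 1 control the name of the day 5 group, and the culture times lie 5 days apart while the stated ages lie 4 days apart. Groups were taken from the treatment label of each sample.

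Per the submitters' processing notes, HISAT2, HTSeq and genome build WBcel235 were used; their versions, the annotation and the handling of reads that map to several places are not given in the sources used here. The table deposited by the authors is named as FPKM, but its values are a signal of another kind: read counts divided by 1 size factor per library, with no correction for gene length. Each value was a whole multiple of 1 step per library within 0.001 reads, in 100% of values, for genes shorter and longer than the median exonic length of 1282 bases alike. The steps, from 0.886 to 1.13, gave back whole reads. The size factors differed by at most 2.05% from median-of-ratios factors computed over the listed genes. The table lists 17076 genes, each with at least 1 read in both age groups; genes outside it were not analysed here. Of the gene IDs, 16887 were found in the table of gene names and 17072 in annotation release 115 of WBcel235, which gave the coordinates, all 1-based. Of the listed genes 16897 are protein-coding and 4280 share exonic bases with another gene. Reads of overlapping, antisense and near-identical genes cannot be assigned with certainty.

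Recovered reads per library were 19645891, 19381185, 19345868 and 20763236 at day 1 and 20743132, 20569012, 21665926 and 22305681 at day 5, in batches 1 to 4. No pair of libraries agreed within sampling noise. At this depth a single read corresponds to a value of about 1, so values of a few units rest on a few reads, and PCR copies cannot be told from separate molecules.

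Before the data were examined, the tests, gene lists, named-gene rule and most alternatives were fixed, for values assumed to be FPKM. The planned test was kept although the unit differed. Genes with a mean value of at least 1 over the 8 libraries (16739) were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with group as the only term, a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment; genes with an adjusted p under 0.05 were called. The count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives added after the unit was known, and called 9303 and 9705 genes; edgeR and limma shared 8977 calls of the same direction. Gene lists from general knowledge, 15 primary and 17 secondary, were tested with camera (preset correlation 0.01, adjusted over the 32 lists), with camera with an estimated correlation, and with fry. Named genes are called genes with non-overlapping groups and a gene symbol: the 6 largest differences in each direction, the 2 largest of each primary list and the largest of each secondary list; where fewer than 2 of a primary list qualified, the member with the highest mean was added.

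Each replicate number is a labelled batch with 1 library per age, so the numbers pair the libraries by their labels. Deviations from the group means of same-batch libraries had correlations across genes of -0.22, 0.24, -0.10 and -0.02, with a mean of -0.03, against 0.01 for libraries of different batches. The main model had no block; a model with the replicate block is among the alternatives. The others were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5, rescaling to a fixed sum per library, median-of-ratios, quantile and top-gene-free scaling, robust or untrended variance, library weights, a test against 1.5-fold, and each library left out in turn. Added after seeing the data were a common library total, each batch left out, the day 1 libraries of batches 1 and 2 or of batches 3 and 4 left out, and a test of 161 families of genes that share a symbol stem. For the test of depth, reads were thinned at random to 19345868 per library in 20 draws. In each alternative camera used the same library weights and variance trend as limma. Every test weighed in the closing observations was also set after the data had been seen.

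The limma script was tested on simulated counts for day 5 against day 1, with 16653 genes tested and 200 changed: of 50 genes at each fold it recovered 0% at 1.5-fold, 10% at 2-fold, 54% at 4-fold and 88% at 8-fold, and 1 of 77 calls was false. With so few genes changed, the adjustment was stricter than in the data, so these shares do not give the power there. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 drew the plots and computed permutation tests.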

Results

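Poly(A)-selected RNA from whole wild-type Caenorhabditis elegans hermaphrodites (strain N2, the standard laboratory strain) was sequenced at 2 ages labelled as adult. Worms labelled adult day 1 had grown for 60 h from synchronized first-stage larvae, and worms labelled adult day 5 for 180 h, both at 20 °C on bacterial lawns. Each age had 4 libraries, 1 from each of 4 labelled batches. The libraries held between 19345868 and 22305681 reads assigned to 17076 listed genes, with 19345868 to 20763236 at day 1 and 20569012 to 22305681 at day 5. Between 16001 and 16573 of the listed genes had at least 1 read in a library. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels are the deposited values, read counts divided by 1 size factor per library, given as mean ± SD over the 4 libraries of an age (n = 4). The log2 differences are day 5 minus day 1 on the log2(value + 1) scale, with the standard error (SE) of the limma fit, and they can understate the change of genes with low values. Where the libraries of an age differ widely, as for vit-5, they can also exceed the ratio of the mean levels.

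The labelled age was the main axis of variation between the libraries. The first principal component held 67.4% of the variance and placed the 4 day 1 libraries between -147.6 and -97.5 and the 4 day 5 libraries between 112.2 and 156.4. The second held 17.3% and spread the day 1 libraries, at 104.5 in batch 1, 75.2 in batch 2, -92.5 in batch 3 and -65.9 in batch 4. Day 5 libraries lay between -53.6 and 23.7 on it. Variation between libraries was larger at day 1, with a median SD over genes of 0.54 (log2), than at day 5, where it was 0.36.

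**Figure D1:**
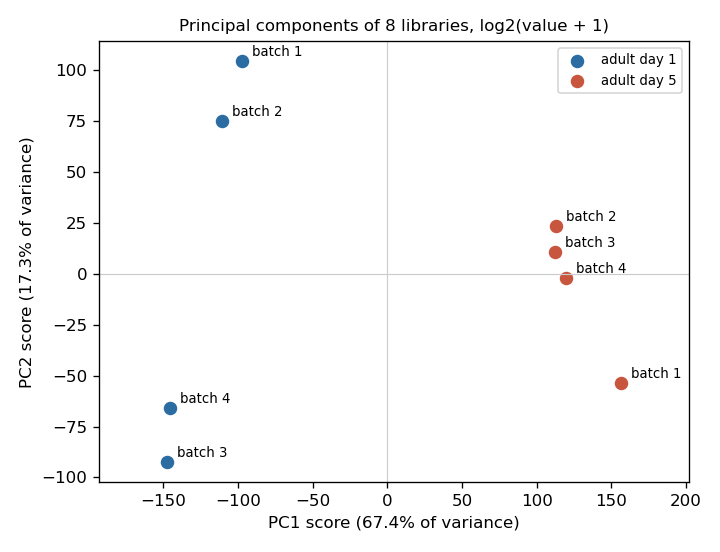
Scores of the 8 libraries on the first (x axis, 67.4% of variance) and second (y axis, 17.3%) principal component of log2(value + 1); each point is 1 library, coloured by age and marked with its batch. The day 1 libraries sit at -97.5 or below on the x axis and the day 5 libraries at 112.2 or above.

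The comparison asked which transcripts differ between worms labelled adult day 5 and adult day 1. The title of the series ties maternal age to the survival of offspring by an epigenetic route. Day 1 libraries were low in yolk and high in moult transcripts, so adult age and developmental stage cannot be told apart here. As lists, yolk, eggshell, oocyte and cell-cycle genes were called higher at day 5, and collagens and moult, muscle and ribosomal protein genes lower, with a preset correlation between genes. With an estimated correlation no list was called. Some members of most lists were not called or went the other way. Of 16739 genes tested with limma, 9307 (55.6%) had an adjusted p under 0.05, 4820 higher at day 5 and 4487 lower. With at least a 2-fold difference there were 7885, of which 4032 were higher and 3853 lower. The groups did not overlap in 8844 of the genes tested (52.8%), against 2.86% by chance for 4 against 4, and 9040 of the called genes (97.1%) had the same sign in all 4 batches. This last share is no separate support, as the genes were called on the same libraries. Tested against a difference of 1.5-fold, 6241 genes were called, 3392 higher and 2849 lower. The balance of calls depended on the scaling: 51.8% of calls were higher with the values as deposited and 44.2% when libraries were scaled on genes outside the 1% with the highest values, and the median over all genes moved from -0.06 to -0.30. List medians are given on the deposited scale and include this shift. As RNA came from whole worms, a changed share of a tissue was not separated from a change within it.

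The yolk proteins had the largest list median on the log2(value + 1) scale. All 6 vitellogenins were higher at day 5, with a median log2 difference of 10.88 (camera adjusted p = 0.000886, and adjusted p = 0.384 with an estimated correlation). The size of this median rested on the day 1 libraries: it was 11.64, 12.16, 9.74 and 9.99 without those of batches 1 to 4 in turn. It was 8.13 without those of batches 3 and 4 and 13.93 without those of batches 1 and 2, and 8.73 with edgeR. vit-2 (WBGene00006926; WBcel235 chromosome X, 5101042 to 5106169) went from 413 ± 645 at day 1 to 282332 ± 111041 at day 5, a log2 difference of 11.78 (SE 1.45, limma adjusted p = 0.000112), and vit-5 (WBGene00006929; X, 3403471 to 3408603) from 128 ± 237 to 224534 ± 82422, at 14.25 (SE 1.71, adjusted p = 9.95e-05). With edgeR they were 9.32 for vit-2 and 10.68 for vit-5. Without the day 1 libraries of batches 1 to 4 in turn vit-2 was at 12.40, 13.17, 10.60 and 10.96, and vit-5 at 16.06 without batch 2 and 13.09 without batch 3 or batch 4. vit-6 (WBGene00006930; IV, 8261157 to 8266459) reached 326326 ± 117101 from 542 ± 821. The day 1 levels differed between libraries: vit-2 was at 273, 1363, 5.50 and 13 in batches 1 to 4, and vit-5 had no reads in batches 3 and 4. By the ratio of the mean levels, col-95 (8811), ule-5 (6636) and ule-1 (5024) rose further than vit-5 (1751) and vit-2 (683). Vitellogenins took 3.07 to 5.56% of the reads in day 5 libraries and at most 0.0234% in day 1 libraries. vit-3, vit-4 and vit-5 are near-identical copies, so how their reads were divided is uncertain.

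Genes of the eggshell and the oocyte rose with them. Of 18 eggshell and egg-activation genes 16 were higher and 2 lower, with a median of 5.26 (camera adjusted p = 4.85e-08, and adjusted p = 0.35 with an estimated correlation). perm-2 (WBGene00016636; IV, 1126790 to 1128865) and perm-4 (WBGene00016638; IV, 1121494 to 1125107), which build the permeability barrier of the eggshell, went from 34.4 ± 39.9 to 20702 ± 3941 and from 86.0 ± 101 to 35242 ± 6784. The lower members were cey-1, a Y-box RNA-binding protein, and nep-1, a peptidase, at -0.47 and -0.61. Of 43 oocyte and germline RNA regulators 38 were higher (39 adjusted over the list alone) and none lower, with a median of 3.31 (camera adjusted p = 1.71e-13, and adjusted p = 0.35 with an estimated correlation). nos-2 (WBGene00003784), a Nanos-family translational regulator, went from 5.77 ± 6.70 to 3379 ± 904, and meg-1 (WBGene00010492), a germ granule protein of the early embryo, from 7.22 ± 6.47 to 2987 ± 742. In nos-2, 154 exonic bases are shared with him-14. The uterine lumen genes ule-5 (WBGene00013394; X, 11883127 to 11884042), ule-1 (WBGene00021005; I, 2219468 to 2222313) and ule-3 (WBGene00008378; V, 10793798 to 10794924) were among the 6 largest increases on the log2(value + 1) scale, from 2.17 ± 2.79 to 14426 ± 3653, from 2.17 ± 1.45 to 10910 ± 3241 and from 11.9 ± 21.3 to 16452 ± 2716. Their log2 differences were 12.602 (SE 0.60), 11.90 (SE 0.46) and 11.87 (SE 0.95), with limma adjusted p of 6.53e-07, 3.58e-07 and 1.06e-05. For ule-3 it was 10.34 with edgeR, 12.99 without the day 1 library of batch 2 and 11.16 without that of batch 4. Counts for a list are over all genes tested, and counts adjusted over the list alone were identical where none is given. Members named because 5 or fewer of a list were called in a direction were chosen after their values were seen.

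In the main fit sperm transcripts were not called as a group. None of the 30 major sperm protein genes was called by limma. The median of 1.297 was not called by camera (adjusted p = 0.17, and adjusted p = 0.842 with an estimated correlation), and the batch medians were -3.72, 0.93, 3.88 and 4.12. msp-40 (WBGene00003435), a highly similar member of this family, was at 1140, 532, 41.8 and 36.8 in the day 1 libraries of batches 1 to 4 and at 73.1, 995, 556 and 573 in those of day 5. Of 35 sperm function genes 1 was higher, spe-39 (495 ± 178 to 1738 ± 274), a vesicle-trafficking gene that acts in many tissues, and 1 lower, spe-4 (290 ± 250 to 58.5 ± 24.8), a presenilin of sperm. Adjusted over the list alone spe-39 was called and spe-4 was not. The median was 0.07 (camera adjusted p = 0.942, and adjusted p = 0.988 with an estimated correlation), with the camera direction downward, and ssq-2 (WBGene00006051) was at 678 ± 806 and 594 ± 374. The sperm function list was called lower without the day 1 libraries of batches 3 and 4, and higher without those of batches 1 and 2. The result for major sperm proteins depended on single libraries, as the list was called higher without the day 1 library of batch 1 (adjusted p = 0.00918) or batch 2 (adjusted p = 0.0486) or the day 5 library of batch 1 (adjusted p = 0.0161). Its median was 2.17, 1.91, 0.63 and 0.54 without the day 1 libraries of batches 1 to 4 in turn, and 2.11 without the day 5 library of batch 1. It turned to -0.94, not called (adjusted p = 0.0964), without the day 1 libraries of batches 3 and 4, rose to 3.55 without those of batches 1 and 2, and was 0.39 with edgeR.

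Cell-division genes were all higher, and meiosis genes mostly. All 72 DNA replication and mitotic cell-cycle genes were higher, with a median of 2.25 (camera adjusted p = 2.88e-22, and adjusted p = 0.302 with an estimated correlation). The B-type cyclins cyb-2.2 (WBGene00000867) and cyb-2.1 (WBGene00000866) went from 175 ± 92.0 to 5962 ± 1152 and from 121 ± 53.7 to 3642 ± 648. They are close copies, and the division of their reads is uncertain. Of 44 meiosis and synaptonemal complex genes 41 were higher and none lower, with a median of 1.87 (camera adjusted p = 2.88e-13, and adjusted p = 0.332 with an estimated correlation). lab-1 (WBGene00007278), which protects cohesion between chromatids, went from 47.3 ± 18.2 to 636 ± 84.2, and dsb-1 (WBGene00008580), needed for meiotic double-strand breaks, from 300 ± 149 to 1630 ± 380. Of 29 early embryonic zygotic genes 19 were higher and 7 lower, with a median of 2.24 (camera adjusted p = 0.00129, and adjusted p = 0.14 with an estimated correlation). vet-2 (WBGene00016453), an early embryonic transcript, went from 2.59 ± 3.004 to 797 ± 259, and lsy-27 (WBGene00009834) was at 0.243 ± 0.486, from a single read, at day 1 and 752 ± 264 at day 5. Among 56 genes of the core histone list, which also holds linker histones and variants, 21 were higher (19 adjusted over the list alone) and 6 lower, a median of 0.79 not called by camera (adjusted p = 0.0684, and adjusted p = 0.541 with an estimated correlation). It was called with rescaling to a fixed sum, quantile normalization or library weights, and without the day 1 libraries of batches 3 and 4. Of 44 genes with the symbol stem his alone, 11 were higher and 6 lower, with a median of 0.21 (camera adjusted p = 0.731 over 161 families). The centromeric histone variant cpar-1 (WBGene00010036) went from 76.6 ± 20.51 to 1277 ± 188. Histone genes are near-identical copies, so single members are uncertain. The libraries were poly(A)-selected, so histone transcripts without a poly(A) tail would be under-counted, which was not tested. The median log2(value + 1) of this list was 4.58 to 5.47 in the libraries. Day 1 libraries that were low in yolk transcripts, those of batches 3 and 4, also had the lowest medians of the oocyte, replication and meiosis lists.

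**Figure D2:**
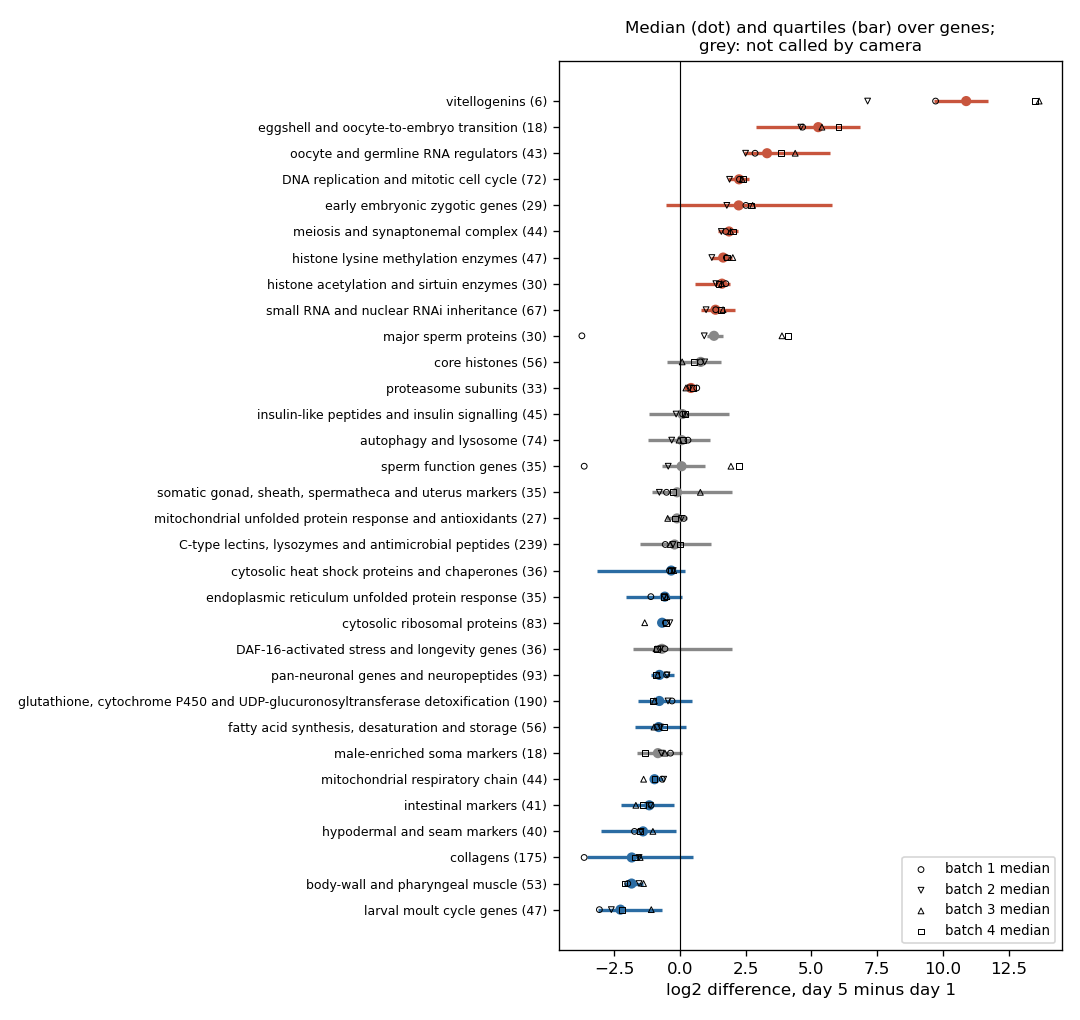
Median log2 difference (x axis, day 5 minus day 1) of each of 32 gene lists (y axis, number of genes tested in brackets), with bars for the quartiles over genes and open symbols for the median within each batch; red and blue mark lists called higher and lower by camera with the preset correlation. Vitellogenins (10.88) and eggshell genes (5.26) stand at the top and larval moult genes (-2.26) at the bottom, and the batch medians of sperm lists lie on both sides of 0.

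Chromatin-modifying enzymes and small RNA genes, the groups nearest to the title of the series, were mostly higher at day 5. Of 47 histone lysine methylation enzymes, writers and erasers of methyl marks, 36 were higher (37 adjusted over the list alone) and 2 lower, with a median of 1.65 (camera adjusted p = 4.85e-08, and adjusted p = 0.35 with an estimated correlation). jmjd-3.2 (WBGene00009089), a histone demethylase of the JmjC family, went from 0.963 ± 1.11 to 185 ± 68.1, and set-13 (WBGene00019690) was at 0.243 ± 0.486, from a single read, at day 1 and 52.1 ± 12.01 at day 5. The lower members were the SET-domain genes set-18 (-2.80) and set-30 (-2.097). Of 30 histone acetylation and sirtuin genes 22 were higher and 2 lower, with a median of 1.60 (camera adjusted p = 2.61e-05, and adjusted p = 0.302 with an estimated correlation). The histone acetyltransferases hat-1 (WBGene00044069) and mys-1 (WBGene00007029) went from 1151 ± 152 to 5887 ± 1252 and from 361 ± 93.2 to 1686 ± 257, log2 differences of 2.34 (SE 0.20) and 2.25 (SE 0.23). The lower members were cbp-3 (-0.63) and the mitochondrial sirtuin sir-2.2 (-1.201). Of 67 small RNA and nuclear RNAi inheritance genes 53 were higher (55 adjusted over the list alone) and 1, the Argonaute sago-2, was lower (-1.27), with a median of 1.35 (camera adjusted p = 4.81e-10, and adjusted p = 0.35 with an estimated correlation). The Argonautes ergo-1 (WBGene00019971) and alg-5 (WBGene00011945) went from 965 ± 539 to 10167 ± 3511 and from 349 ± 153 to 2664 ± 499. The meiosis list, germline genes outside these groups, had a median of 1.87 in the same libraries.

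Many cuticle and moulting genes were lower, and others were higher or not called. Of 175 collagens 91 were lower and 29 higher (93 and 32 adjusted over the list alone), with a median of -1.83 (camera adjusted p = 0.00028, and adjusted p = 0.591 with an estimated correlation). col-54 (WBGene00000631; I, 5842709 to 5844050) went from 3550 ± 3181 to 98.6 ± 69.5, at -5.02 (SE 0.94, limma adjusted p = 0.00138), or -5.77 without the day 1 library of batch 1 and -4.26 without the day 5 library of batch 1. col-95 (WBGene00000670) rose, from 0.477 ± 0.953, from 2 reads, to 4200 ± 1875, and so did col-143 (WBGene00000716), from 4.25 ± 2.57 to 5949 ± 3240. Of 47 larval moult genes 33 were lower (34 adjusted over the list alone) and 3 higher, with a median of -2.26 (camera adjusted p = 5.68e-06, and adjusted p = 0.35 with an estimated correlation). The higher members were cutl-2, phat-3 and hch-1 (WBGene00001828), the astacin protease of hatching, at 0.477 ± 0.953 and 555 ± 286. Of 40 hypodermal and seam markers 26 were lower and 6 higher, with a median of -1.40 (camera adjusted p = 0.00073, and adjusted p = 0.35 with an estimated correlation), and the larval cuticle collagen dpy-7 (WBGene00001069) went from 3935 ± 1073 to 251 ± 137. The day 5 library of batch 1 had the lowest collagen median, 6.87, against 8.97 to 9.10 in the other day 5 libraries. In the day 1 libraries of batches 1 to 4 it was 9.06, 9.17, 8.71 and 8.525. By this measure the other day 5 libraries lay within the day 1 range.

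Muscle and intestinal markers were mostly lower, and neuronal genes in part. A smaller share of these tissues in the RNA was not separated from a fall within them. Of 53 muscle genes 46 were lower, with a median of -1.83 (camera adjusted p = 3.68e-11, and adjusted p = 0.303 with an estimated correlation), and the troponin T gene tnt-4 (WBGene00006589) went from 2515 ± 896 to 254 ± 113. The higher members were act-2, an actin, and mlc-4, a non-muscle myosin light chain, and 3 were higher adjusted over the list alone. Of 93 neuronal genes 42 were lower and 7 higher, with a median of -0.78 (camera adjusted p = 0.000254, and adjusted p = 0.445 with an estimated correlation). It was -0.40 without the day 1 libraries of batches 3 and 4 (adjusted p = 0.0087). tbh-1 (WBGene00006541), which makes octopamine in neurons and in gonadal sheath cells, rose from 12.8 ± 5.00 to 4224 ± 761 (log2 difference 8.33, SE 0.33); it shares 372 exonic bases with H13N06.7, and without strand-marked counting its reads are uncertain. Of 41 intestinal markers 24 were lower and 6 higher (25 and 7 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 1.67e-05, and adjusted p = 0.133 with an estimated correlation), and 20 of these genes are also in other lists. The cathepsin B-like protease cpr-5 (WBGene00000785; V, 1132598 to 1134036) fell from 20638 ± 6406 to 362 ± 226, at -6.07 (SE 0.51, limma adjusted p = 1.37e-05). Of 35 somatic gonad markers 10 were higher and 9 lower (8 adjusted over the list alone), with a median of -0.11 whose sign turned with quantile normalization (camera adjusted p = 0.875, and adjusted p = 0.988 with an estimated correlation, camera and mean directions upward). The innexin inx-22 (WBGene00002144), a gap-junction protein of oocytes although placed in this list, went from 125 ± 68.8 to 2340 ± 489. Of 18 male soma markers 7 were lower and 2, dmd-5 and tra-4, higher, with a median of -0.84 not called by camera (adjusted p = 0.151, and adjusted p = 0.384 with an estimated correlation); mab-3 (WBGene00003100), a DM-domain transcription factor, went from 192 ± 93.2 to 25.8 ± 12.07.

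**Figure D3:**
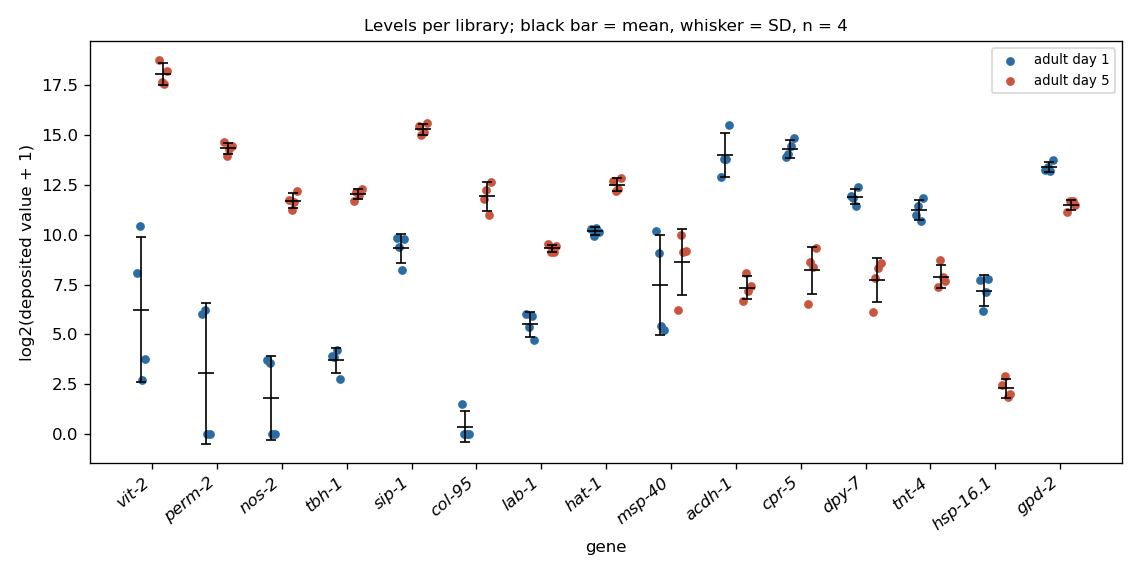
Level of 15 named genes in each library as log2(deposited value + 1) on the y axis (a log scale), with points for libraries, bars for the mean and whiskers for the SD (n = 4) at each age. Yolk and eggshell genes such as vit-2 and perm-2 lie far higher at day 5, acdh-1 and cpr-5 lie lower, and the ages overlap for msp-40.

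Most ribosomal protein and respiratory chain genes were called lower, as were 28 of 56 fatty acid genes, and 15 of 33 proteasome genes were called higher. Of 83 cytosolic ribosomal protein genes 53 were lower (58 adjusted over the list alone) and none higher, with a median of -0.67 (camera adjusted p = 4.53e-07, and adjusted p = 0.591 with an estimated correlation). The median was -0.24 with quantile normalization (adjusted p = 0.0176), -0.36 without the day 1 libraries of batches 3 and 4 and -1.05 without those of batches 1 and 2, and the batch medians were -0.55, -0.38, -1.34 and -0.53. The gene rpl-37 (WBGene00004451), named for its large difference (-2.23), went from 165 ± 89.7 to 33.3 ± 15.3. The median log2(value + 1) of the list was 14.3 to 15.7 in the libraries, so rpl-37 lies far below a typical member. Of 44 respiratory chain genes 34 were lower (37 adjusted over the list alone) and 3 higher, with a median of -0.96 (camera adjusted p = 1.10e-06, and adjusted p = 0.407 with an estimated correlation). Without the day 1 libraries of batches 3 and 4 this median was -0.62. asg-2 (WBGene00000210), an ATP synthase subunit, went from 8263 ± 4294 to 1252 ± 336, and the higher members were asb-1, ucr-2.3 and nduf-2.2. Of 56 fatty acid genes 28 were lower and 7 higher, with a median of -0.81 (camera adjusted p = 0.00103, and adjusted p = 0.175 with an estimated correlation). acdh-1 (WBGene00016943; I, 6497436 to 6499560), an acyl-CoA dehydrogenase of propionate breakdown, fell from 20490 ± 17541 to 173 ± 72.7, at -6.63 (SE 0.51, limma adjusted p = 7.72e-06), the largest decrease on this scale among the genes named by the rule. By the ratio of the means nhr-234 fell further. Of 33 proteasome genes 15 were higher and none lower, with a median of 0.42 (camera adjusted p = 0.00507, and adjusted p = 0.591 with an estimated correlation), and rpn-1 (WBGene00004458) went from 5007 ± 1552 to 10533 ± 1681. The call of the proteasome list was lost with quantile normalization (adjusted p = 0.0679), with scaling outside the top 1% (adjusted p = 0.0558) and without the day 1 libraries of batches 1 and 2 (adjusted p = 0.103). Of 74 autophagy and lysosome genes 27 were higher (28 adjusted over the list alone) and 30 lower, a median of 0.07 whose sign depended on the scaling (camera adjusted p = 0.839, and adjusted p = 0.966 with an estimated correlation, camera and mean directions downward).

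Stress, detoxification and immune genes moved in both directions. Of 190 detoxification genes 82 were lower and 29 higher (30 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 0.00131, and adjusted p = 0.453 with an estimated correlation), and gst-30 (WBGene00001778), a glutathione S-transferase, went from 7.66 ± 4.27 to 645 ± 428. Without the day 1 libraries of batches 3 and 4 the detoxification median was -0.49. Of 36 cytosolic chaperones 14 were lower and 6 higher, with a median of -0.33 (camera adjusted p = 0.036, and adjusted p = 0.591 with an estimated correlation). The inducible small heat shock gene hsp-16.1 (WBGene00002017; a second gene ID carries the same symbol) fell from 160 ± 70.6 to 4.17 ± 1.76, while sip-1 (WBGene00004798), a small heat shock gene of the germline and embryo, rose from 689 ± 278 to 40135 ± 7798. The call of this list was lost without the day 1 library of batch 1 (adjusted p = 0.0868) or the day 5 library of batch 3 (adjusted p = 0.0552), with a minimum mean of 5 (adjusted p = 0.05), without a variance trend (adjusted p = 0.0582), without batch 1 (adjusted p = 0.0531) and without the day 1 libraries of batches 1 and 2 (adjusted p = 0.0628). Of 35 genes of the unfolded protein response of the endoplasmic reticulum 18 were lower and 5 higher, with a median of -0.57 (camera adjusted p = 0.013, and adjusted p = 0.453 with an estimated correlation). abu-6 (WBGene00000029) went from 476 ± 304 to 41.4 ± 28.7, and the higher members were ire-1, sel-11, cdc-48.1, sel-1 and ero-1. Of 12 genes tested with the symbol stem abu, that of abu-6, 10 were lower and 0 higher. The list was not tested without abu genes, so how far its call rests on them is not known. Of 27 mitochondrial stress and antioxidant genes 5 were lower and 3 higher (2 adjusted over the list alone), a median of -0.11 not called by camera (adjusted p = 0.437, and adjusted p = 0.803 with an estimated correlation). The lower ones were hsp-60, prdx-3, dve-1, gpx-5 and gpd-2 (WBGene00001684; 10740 ± 1890 to 2928 ± 470), a glycolytic enzyme, and the higher ones sod-5, atfs-1 and sod-4.

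Neither the longevity nor the immune list was called as a group. Of 36 genes activated by DAF-16, the transcription factor of the insulin pathway, 17 were lower and 11 higher, with a median of -0.68 (camera adjusted p = 0.162, and adjusted p = 0.591 with an estimated correlation); 18 of them are also in other lists. Of 239 C-type lectins, lysozymes and antimicrobial peptides 78 were lower (79 adjusted over the list alone) and 58 higher, with a median of -0.20 and a mean of 0.04 (camera adjusted p = 0.309, downward, and adjusted p = 0.675 with an estimated correlation). The largest differences in it were increases, in clec-266 (WBGene00016088), from 4.86 ± 2.65 to 5573 ± 2532, which shares 371 exonic bases with kqt-1, and in clec-74 (WBGene00021585), from 7.84 ± 8.06 to 1602 ± 1258. Of 45 insulin-like peptides and insulin signalling genes 15 were higher and 12 lower, a median of 0.09 whose sign depended on the scaling (camera adjusted p = 0.792, and adjusted p = 0.815 with an estimated correlation), and ins-19 (WBGene00002102) went from 1.58 ± 2.09 to 514 ± 233. Large decreases outside the lists were seen in the neighbouring nuclear hormone receptor genes nhr-234 (WBGene00012596; II, 12636678 to 12638491), from 90.2 ± 41.3 to 0.482 ± 0.557, from 2 reads, and nhr-235 (WBGene00012597; II, 12640670 to 12642917), from 93.9 ± 55.7 to 1.79 ± 1.57. idpc-7 (WBGene00011537; V, 9618231 to 9619019) went from 972 ± 543 to 43.05 ± 31.04, at -5.29 (SE 1.25, limma adjusted p = 0.00512). It was -4.47 with edgeR, and -3.83 and -5.89 without the day 5 library of batch 1 or batch 3. The limma adjusted p was 1.14e-05 for nhr-234 and 9.25e-05 for nhr-235. Across the 32 lists camera called 22 with the preset correlation of 0.01, 10 higher and 12 lower, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05; fry, which tests each list by itself, called 24.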

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

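All tests weighed here were chosen only after the results were seen. Libraries far from the others of their age were looked for in 178 groups of 4 values with Dixon's ratio at its critical value for 4 samples. There were 15, against about 8.9 expected by chance. Of these, 8 lay in the day 5 library of batch 1, which stood apart in collagens (median log2(value + 1) of 6.87, others 8.97 to 9.10), hypodermal markers (7.83, others 8.56 to 8.65), neuronal genes (7.48, others 7.70 to 7.74), small RNA genes (11.06, others 10.55 to 10.60), ule-3 (14.32, others 13.85 to 13.90), mys-1 (11.01, others 10.58 to 10.64), idpc-7 (0.0, others 5.48 to 6.20) and abu-6 (0.0, others 5.49 to 5.97). The day 5 library of batch 4 was high in respiratory chain genes (11.89, others 11.61 to 11.64). The day 1 library of batch 3 was low in histone acetylation genes (9.20, others 9.60 to 9.67) and in ule-1 (0.0, others 1.95 to 1.97). Low read numbers gave the other flags at day 1: lsy-27 and set-13 at 0.98 in batch 2, and col-95 and hch-1 at 1.54 in batch 1, each against 0.0 in the other libraries.

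The day 1 libraries were low in vitellogenin and high in moult-cycle transcripts. The highest day 1 value of vit-2 was 0.714% of its lowest day 5 value, and the moult-cycle list was lower at day 5 in all 4 batches. Abundant day 5 transcripts taking reads from all others are argued against as the cause, since the moult list stood at -2.51 when scaled on genes outside the top 1%. Collection of day 1 worms before adult reproductive transcription had begun remains a candidate explanation, and adult age as such, which the design names, is untested, since stage and group coincide.

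The day 1 libraries spread over the second principal component. A batch effect shared by both ages is argued against, as libraries of the same batch deviated together (correlation over 0.1) in 1 of 4 batches, and so is depth. The day 1 library of batch 3, lowest on this component, had the fewest reads, but that of batch 4, also low on it, had the most of this age (20763236). With all libraries thinned to 19345868 reads the gap between batches 1 and 2 and batches 3 and 4 kept at least 99.3% of its 141.15 in 20 draws. Thinning took only a small part of the day 1 reads, so it adds little. A different developmental time of the day 1 cultures stays open. In 4 of 4 lists (vitellogenins, eggshell, oocyte, major sperm proteins) the day 1 libraries of batches 1 and 2 lay above those of batches 3 and 4, but so did the moult-cycle list (10.29 and 10.46 against 9.48 and 9.91), which older cultures would be expected to have lower. Moult transcripts rise and fall, so this does not exclude it. The order had been seen in part, and no independent staging of the worms was used here.

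Most histone-modifier and small RNA genes were called higher at day 5 and a few lower, and with an estimated correlation none of these lists was called. The scaling of the libraries alone is argued against, because the histone methylation list stood at 1.39 when scaled on genes outside the top 1%. A larger share of germline RNA at day 5 may account for the rise: the methylation list lay 0.22 below the meiosis list (difference -0.224, 95% bootstrap interval over genes -0.536 to 0.14). The acetylation list differed by -0.27 (-0.87 to 0.118) and the small RNA list by -0.516 (-0.847 to -0.047). Genes are not independent, and regulation of these enzymes within the germline stays open, as does age. Of 29 early embryonic zygotic genes 19 were higher and 7 lower at day 5, with a median of 2.24. RNA of embryos inside the worms was not separated from germline RNA.

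Chance in how libraries were assigned to ages was tested over the 35 splits of the 8 libraries into 4 and 4. For the number of genes called, 1 of 35 splits, the real one, reached 9307, and the highest other count was 0. For genes with a 2-fold difference 1 split reached 7885 and the highest other was 0. The 8 splits that part every batch are too few for a share under 0.05, and among them the highest other was also 0. Every split but the real one mixes the ages, which adds any difference between ages to the spread within groups and lowers the count. A share of 1 of 35 is the smallest possible, and the test was chosen after the counts were seen. It therefore does not exclude chance. For lists called by camera, 9 splits gave at least the real 22, up to 26, so chance cannot be excluded by this count alone. The 8 others of these 9 were among the 16 splits that keep 3 day 1 libraries together. Those splits still carry part of the difference between the ages. The 18 splits with 2 libraries of each age on each side called 4 to 15 lists, though limma called 0 genes in each. With the preset correlation lists were thus called without a net contrast of the ages.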

How the results depend on the processing

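Alternatives named as added in the account of processing were chosen after seeing the data. The 9307 calls became 7247 to 10383 under the alternatives other than the test against 1.5-fold, and 8251 to 9448 with 1 library left out; no called gene was called in the opposite direction under any of them. Under the replicate block (the paired model) 8810 genes were called, 8673 of them shared with the unblocked model in the same direction, and all 22 lists called by camera were kept, so the block changed no list call. The test against 1.5-fold called 6241 genes, 3392 higher in place of 4820 and 2849 lower in place of 4487, as its null is stricter. With an estimated correlation camera called 0 lists in place of 22 (5 with an unadjusted p under 0.05; fry called 24), with adjusted p from 0.133 to 0.591 for the 22 and estimated correlations from -0.00738 to 0.926; the cause was not tested. The sperm function list turned from 0.07 to -1.46 (adjusted p = 0.000818) without the day 1 libraries of batches 3 and 4 and was higher at 1.87 (adjusted p = 0.00302) without those of batches 1 and 2, so its direction rests on which day 1 libraries are used. The lists were not tested against 1.5-fold or with DESeq2, and robust variance does not enter camera. Of the 22 lists called, 20 kept call and direction under every alternative run on the lists other than the estimated correlation, and the heat shock and proteasome lists lost the call under some. Of the 10 not called, 7 were called under none and the core histone, major sperm protein and sperm function lists under some. In 4 of these 7 (somatic gonad, mitochondrial stress, autophagy and insulin lists) the median or the camera direction turned, so no direction is claimed for them, nor for the major sperm protein list, whose median turned to -0.94 without the day 1 libraries of batches 3 and 4. As log2 values, medians of called lists moved by over 1.5 times with quantile normalization (small RNA 0.88, ribosomal proteins -0.24, proteasome 0.15), with scaling outside the top 1% (chaperones -0.58, proteasome 0.17), without the day 1 libraries of batches 3 and 4 (unfolded protein response of the endoplasmic reticulum -0.93, detoxification -0.49, respiratory chain -0.62, ribosomal proteins -0.36, neuronal genes -0.40) and without those of batches 1 and 2 (chaperones -0.21, ribosomal proteins -1.05). As folds, medians also moved by over 1.5 times for early embryonic genes (3.06 with a pseudocount of 0.1, 1.51 with rescaling to a fixed sum), oocyte genes (2.70 with library weights, 2.63 without the day 1 libraries of batches 3 and 4, 4.12 without those of batches 1 and 2), eggshell genes (4.61 without those of batches 3 and 4) and vitellogenins (10.28 with a pseudocount of 5, 9.46 with rescaling to a fixed sum, 8.47 with library weights, 8.73 with edgeR, 12.13, 9.956 and 9.998 without batches 2, 3 and 4, and 8.13 to 13.93 without day 1 libraries). As folds, many named genes moved by over 1.5 times: 15 with edgeR, 16 with DESeq2, 12 with library weights, 19 and 23 with pseudocounts of 0.1 and 5, 28 with rescaling to a fixed sum, and 19 without the day 1 libraries of batches 3 and 4 or of batches 1 and 2. With edgeR vit-5, vit-2, vit-6, ule-3, nos-2, perm-2, perm-4, idpc-7 and abu-6 changed less, and nhr-234, lsy-27, jmjd-3.2, set-13, col-95 and hch-1 more. As log2 values, rescaling to a fixed sum per library lowered the log2 differences of 10 named genes with mean values under 5 in 1 age by over 1.5 times (set-13 from 5.46 to 1.77), set-13 also moved with a pseudocount of 5 (3.43), and rpn-1 moved from 1.12 to 0.74 without the day 1 libraries of batches 3 and 4. Moves under the fixed sum also hold the greater weight of the pseudocount there, so they do not show dependence on the library scaling alone. Core histones were called with rescaling to a fixed sum per library (adjusted p = 0.0226), with quantile normalization (adjusted p = 0.0231), with library weights (adjusted p = 0.0199) and without the day 1 libraries of batches 3 and 4 (adjusted p = 0.0256); the cause was not tested. Of 51 named genes 49 kept call and direction; msp-40 and ssq-2, not called, were called higher without the day 1 libraries of batches 1 and 2. Same-batch correlations stayed within 1 SD of their mean of -0.03 (from -0.15 to 0.09). In simulations with 200 genes changed, differences of 2-fold were mostly missed. With 77 calls there against 9307 here, the adjustment was stricter than in the data, so this does not give the power of the comparison. Among genes not called the 95th percentile of the absolute log2 difference was 1.49, so they are not shown to be unchanged.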

Other observations

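All tests in this part were chosen after the results were seen. Beyond the fixed lists, genes that share a symbol stem were tested as 161 families: 65 were called by camera with the preset correlation, 25 higher and 40 lower, and 0 with an estimated correlation (lowest adjusted p = 0.416), so they are exploratory. Among F-box genes of the fbxb family 31 of 34 were higher, with a median log2 difference of 4.11. Nucleoporins (npp, 24 of 25 higher, median 1.52), Integrator subunits (ints, 11 of 11, 1.44), TBP-associated factors (taf, 15 of 17, 1.67) and Mediator subunits (mdt, 17 of 20, 1.34) were mostly higher. Ligand-gated ion channels (lgc, 28 of 50 lower, median -1.38), potassium channels (twk, 28 of 43, -1.31), nuclear hormone receptors (nhr, 77 of 232, -0.64), vacuolar ATPase subunits (vha, 17 of 20, -1.08), patched-related genes (ptr, 16 of 24, -2.12) and the hedgehog-related grd genes (12 of 15, -3.21) were mostly lower or lower in part. None of these medians turned sign under the 5 scalings tried, but 3 log2 values moved by over 1.5 times: fbxb to 1.37 and lgc to -0.79 with rescaling to a fixed sum per library, and ints to 0.905 with quantile normalization. As a fold grd also moved, to -2.15 with that rescaling. The fixed sum also shrinks low values. With a common library total fbxb was at 4.05, lgc at -1.46 and grd at -3.29.

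X-linked genes were lower at day 5 than autosomal ones. Of 2405 X-linked genes tested 17.01% were higher and 39.9% lower, against 30.8% and 24.6% of 14320 autosomal genes; the medians were -0.605 and 0.035, and the autosomal one turned sign under 4 of the 5 scalings. The autosomes were not alike: chromosome V went the same way as X, less far, with 22.87% higher, 30.48% lower and a median of -0.387 (from -0.602 to -0.195 under the scalings). The -0.195 came from rescaling to a fixed sum, which also shrinks low values, and with a common library total the median was -0.449. Without vitellogenins, X-linked genes held 11.49, 11.93, 9.31 and 10.97% of the values in day 1 libraries and 6.34, 6.96, 6.85 and 6.41% in day 5 libraries of batches 1 to 4. The difference was -4.28 percentage points (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows), and the share was lower in 4 of 4 batches. A larger share of germline RNA at day 5 may account for it, since the X chromosome is largely silent in much of the germline; a fall of somatic X-linked transcripts within their tissues was not separated from it, and the fall on chromosome V was not tested against any explanation.

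Genes of the propionate shunt, the route of propionate breakdown used when vitamin B12 is scarce, were lower at day 5. The list was written after acdh-1 had been seen. Of 7 genes 5 were called lower with limma (acdh-1, hphd-1, ech-6, nhr-68 and hach-1), and the median was -2.44. Of 14 methionine cycle and related genes 6 were lower and 1 higher, with a median of -0.57. A change of the whole vitamin B12-responsive programme could not be decided: the 5 lower shunt genes met the test, but the methionine list, for which a median above 0 had been set, did not, and the direction set for that list is itself uncertain. acdh-1 was at 7599, 13932, 14016 and 46413 in the day 1 libraries and at 102, 273, 143 and 172 in those of day 5.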
